A study of Mus musculus with 4 samples.

How the data were processed

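RNA was sequenced from lung tissue around B16-F10 metastases of 2 wild-type mice and 2 Lf knockout mice, 1 library per mouse. Per the labels, RNA was isolated with a kit for small and total RNA and made into standard Solexa libraries. The deposited values are FPKM, fragments per kilobase of transcript scaled to the mapped fragments of the library, with 1 value per gene symbol and library. TopHat, Cufflinks, HTSeq, DESeq and the genome build GRCm38 are named in the submitters' processing notes, without a version or role for any of them. Which tool made the FPKM values, the annotation behind them, the strand setting and any scaling between libraries are not given in the sources used here. How reads that match several places were counted is likewise not given, so genes with near-identical copies are uncertain.

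Each library listed 21545 symbols. The 46 extra entries of 39 repeated symbols were summed by symbol, which left 21499 genes. Positions came from the GENCODE vM21 annotation of GRCm38, in which 20931 symbols (97.4%) had a unique position. Values were used as deposited, with no further scaling. Read totals are unknown, and FPKM gives neither counts nor counting intervals. Relative depth was estimated from the ratios of low values (FPKM up to 0.3) between libraries, over 1218 to 1361 genes a pair. Values near 0 are not always absence: 14 genes were listed at 0 in some library and at 10 or more in another.

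Genes with an FPKM of at least 1 in at least 2 libraries were tested, which left 12573. The values were taken as log2(FPKM + 1), a scale that understates the change of low genes. Genotypes were compared with limma 3.58.1 in R 4.3.3 (lmFit, and eBayes with a mean-variance trend), with genotype as the sole term and Benjamini-Hochberg adjustment at 0.05. The fit had 2 residual degrees of freedom and 2.62 prior degrees of freedom. An exact two-sided permutation test of 2 mice against 2 cannot give a p below 0.333, so none is given for single genes. Genes at least 2-fold apart whose libraries did not overlap between genotypes were counted as a description by size. The mouse numbers name separate animals in each genotype and were not used as pairs.

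Gene lists of cell types and pathways, 37 in all, were tested with limma's camera at a preset correlation of 0.01 between genes, and again with an estimated correlation. With an estimated correlation camera has only the 2 residual degrees of freedom. A call lost there does not by itself show that the members of a list vary together. Ltf was left out of every list, and the 36 lists with at least 5 tested members were tested, with adjustment over the lists. The lists, the tests, the filter and the rule for named genes were fixed before the data were examined. The rule takes Ltf, then up to 12 genes per direction past the threshold with the largest difference, filled with non-overlapping genes at least 2-fold apart of smallest p. It adds up to 4 members of each list with the smallest p, and Xist and Y-linked genes as a check of sex. Unnamed gene models, immunoglobulin and T cell receptor segments and mitochondrially encoded genes were skipped in naming and kept in counts. Genes named outside the rule are said to have been chosen after their values were seen.

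The limma step was tested on simulated data over 12573 genes, with 100 changed genes per size in each of 5 simulations of the genotype comparison. It recovered 63.6% of genes changed by 1 and 99% of those changed by 3 on the log2 scale, with a mean of 15 false calls. The noise was normal and took limma's moderated variances as true, so the share recovered can be too high for these data. In the data Uty, with a log2 difference of 2.02, had an adjusted p of 0.187 by limma. With the B cell list shifted by 0.5, camera called it in 20 of 20 simulations, and 14 of 700 tests of other lists were called. Noise there was independent between genes, whereas the correlation estimated in the data was 0.39 for this list. These simulations therefore do not measure how often lists are called falsely in the data. Near-identical copies were searched with BLAST 2.17.0 among annotated transcripts, at an identity of at least 95% over at least 50% of the transcript. Tables and figures were made with Python 3.11.15, pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9.

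The alternatives were pseudocounts of 0.1 and 0.5, no filter, a mean FPKM of at least 5, median ratio scaling, quantile normalization, and leaving out haemoglobin, immunoglobulin and the 20 most abundant genes with rescaling. Others were a constant prior variance, robust eBayes, a threshold of 0.1, the mouse number as a replicate block, the estimated correlation and leaving out each library in turn. Leaving out chromosomes X and Y, immunoglobulin genes, or chromosome 17 between 20 and 40 Mb were alternatives chosen after seeing the data.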

Results

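RNA was sequenced from lung tissue of 4 mice that carried B16-F10 metastases. B16-F10 is a mouse melanoma line that seeds the lung when it is injected into the tail vein. The labels describe C57B/L6 males, 8 weeks old at injection, that received 200000 cells and were killed 3 weeks later. The tissue was taken around the metastatic colonies and left the tumour out, according to the labels. Of 10 mice per genotype, 2 wild-type mice and 2 mice lacking lactoferrin (Lf knockout) have a library here. Lactoferrin, the product of Ltf, is an iron-binding protein of neutrophil granules and of mucosal secretions. The question is how the lung around melanoma metastases differs when lactoferrin is missing.

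Each library is a list of FPKM values for 21499 distinct gene symbols. The values summed to 400153 and 375543 in wild-type mice 1 and 2, and to 388799 and 317976 in knockout mice 1 and 2. Scgb1a1 was listed at 0 in knockout mouse 2. Without this gene the sums were 327216 and 315088.5 in wild type and 318818 and 317976 in the knockout. Between 12231 and 12590 genes reached an FPKM of 1 in a library. Total read counts are not given with FPKM, so the absolute depth is unknown. Steps between low values put the depth of wild-type library 2 at 1.11 times, and that of knockout library 1 at 0.969 times, that of wild-type library 1. The steps of knockout library 2 were blurred, with a peak at 1.34 times. Libraries correlated across 12573 genes with Pearson's r between 0.936 (wild type 2 and knockout 2) and 0.964 (wild type 2 and knockout 1), although genes are not independent replicates.

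The knocked-out gene followed the labels. Ltf (chromosome 9, 111019271 to 111042767, plus strand, GRCm38) had an FPKM of 79.2 and 7.32 in wild-type mice 1 and 2, against 0.104 and 0.533 in knockout mice 1 and 2. Both knockout libraries lay below both wild-type libraries, with a log2 difference of -4.31 (SE 1.09). The 2 wild-type mice lay so far apart that the adjusted p was 0.89 in limma's moderated test. The difference was -2.68 without wild-type mouse 1 and -5.95 without wild-type mouse 2.

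The 2 genes that passed the threshold in the higher direction lie on the Y chromosome. Eif2s3y, a translation initiation factor subunit (chromosome Y, 1010543 to 1028847), had an FPKM of 24.2 and 22.0 in the knockout mice and 0.0426 and 0 in the wild-type mice (log2 difference 4.56, SE 0.13, adjusted p = 0.0103). Ddx3y, an RNA helicase (chromosome Y, 1260771 to 1286629), had 14.5 and 12.1 against a listed 0 in both wild-type mice (log2 difference 3.83, SE 0.15, adjusted p = 0.0241). Uty had 3.04 and 3.09, and Kdm5d 2.35 and 1.91, in the knockout mice, and both were listed at 0 in the wild-type mice; neither passed (adjusted p = 0.187 and 0.377). The labels call all 4 mice male. Xist, which the naming rule also holds as a check of sex, is not reported here. X-linked genes known to escape silencing in females lay higher in both wild-type mice, and were chosen after their values were seen. Kdm6a measured 9.19 ± 0.39 in wild type and 4.72 ± 0.14 in the knockout (SD, n = 2), and Kdm5c 18.1 ± 0.06 and 10.4 ± 0.13. Eif2s3x measured 4.94 ± 0.17 and 2.81 ± 0.40, and Ddx3x 102 ± 8.24 and 71.8 ± 10.4 (adjusted p between 0.582 and 0.89 for these 4). Genotype and the presence of Y-linked transcripts therefore cannot be told apart in any comparison of these libraries.

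Of 12573 genes tested, 2 were higher (Eif2s3y and Ddx3y) and 1 was lower (Rpl29) in the knockout at an adjusted p under 0.05 by limma. At an unadjusted p under 0.05, 320 genes were higher and 322 lower, against 432 and 251 after quantile normalization. These 642 genes compare with 967 when wild-type mouse 1 and knockout mouse 2 are set against the other mice. The remaining split gave 203, so the genotype count does not stand out. Rpl29, a protein of the large ribosomal subunit (chromosome 9, 106429454 to 106431568, 4.59 Mb from Ltf), had an FPKM of 90.3 and 174 in the wild-type mice and 0.24 and 0 in the knockout mice (log2 difference -6.83, SE 0.34, adjusted p = 0.0489). Its near-identical processed pseudogene Gm10709, named after its values were seen, had 6.98 and 19.98 in the wild-type mice and was listed at 0 in both knockout mice. The annotation holds 25 near-identical copies of Rpl29, of which 3 are in the files, so the level of Rpl29 is uncertain. No gene passed without wild-type mouse 1, wild-type mouse 2 or knockout mouse 2. None passed with chromosomes X and Y left out, an alternative chosen after seeing the data that removes Eif2s3y and Ddx3y. With no filter no gene passed, and at a mean FPKM of at least 5 Ddx3y did not. Rpl29 did not pass with a pseudocount of 0.1, median ratio scaling, quantile normalization, a constant prior variance or robust eBayes. Without knockout mouse 1 the gene that passed was Scgb1a1, listed at 0 in knockout mouse 2.

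**Figure D1:**
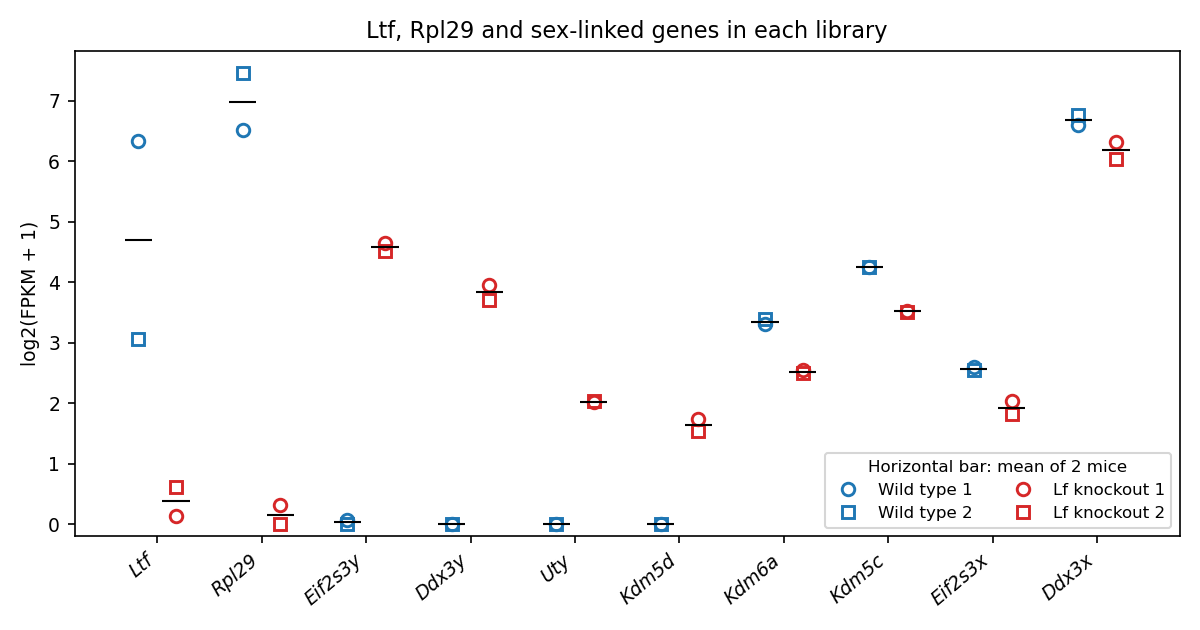
Each point is 1 library's log2(FPKM + 1) for Ltf, Rpl29, 4 Y-linked genes and 4 X-linked genes, with wild-type mice in blue and Lf knockout mice in red; horizontal bars are means of 2 mice. Ltf and Rpl29 are near 0 in both knockout mice, the Y-linked genes are near 0 in both wild-type mice, and the X-linked genes lie higher in both wild-type mice.

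By size, the knockout lung had more genes below wild type than above it. Both knockout libraries lay outside both wild-type libraries with at least a 2-fold difference for 132 genes in the lower direction and 17 in the higher direction. Chance puts 1 in 6 genes in such an order per direction before the fold limit. The 149 genes of both directions compare with 190 when wild-type mouse 1 and knockout mouse 2 are set against the other mice, and with 60 for the remaining split. Immunoglobulin genes made up 76 of the 132, and 56 were other genes. Leaving a library out moved the lower count to between 157 and 319 and the higher count to between 24 and 72.

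The named genes of this kind with the smallest p did not pass the threshold. Lower in the knockout were Prg2, the eosinophil major basic protein (4.96 ± 2.10 in wild type, 0.201 ± 0.19 in the knockout, adjusted p = 0.582), and Marco, a scavenger receptor of macrophages (18.9 ± 1.15 and 2.07 ± 2.15, adjusted p = 0.789). Chil1, a chitinase-like protein, measured 394 ± 64.1 and 169 ± 21.8, and Slamf8 1.99 ± 0.63 and 0.442 ± 0.02. The plasma proteins Ahsg (2.38 ± 0.51 and 0.441 ± 0.02) and Fgg (2.94 ± 1.01 and 0.509 ± 0.18) were of the same order. So were Nr4a3, an orphan nuclear receptor (2.57 ± 0.24 and 0.743 ± 0.13), and Pxylp1 (3.31 ± 0.16 and 1.17 ± 0.35). The GABA receptor subunit Gabra3, on chromosome X, measured 2.58 ± 0.64 and 0.431 ± 0.20. Higher in the knockout were Rprml (4.37 ± 2.04 and 23.3 ± 0.10, adjusted p = 0.582), Arhgap40 (0.538 ± 0.17 and 3.06 ± 0.60), the matricellular protein gene Cyr61 (36.9 ± 11.1 and 77.1 ± 13.3) and Egr1, an immediate early transcription factor (8.25 ± 3.44 and 17.6 ± 6.28). Procr, the endothelial protein C receptor, measured 5.34 ± 0.40 and 20.1 ± 14.4, Nptx1 3.61 ± 1.70 and 8.57 ± 0.08, Npff 0.36 ± 0.13 and 1.85 ± 0.78, and Serpina3m 1.37 ± 0.002 and 4.83 ± 3.16. All values are FPKM as mean ± SD with n = 2.

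Immunoglobulin transcripts were lower in both knockout mice. Of 155 tested immunoglobulin genes, a group formed after their values were seen, 142 lay lower, 89 of them with both knockout libraries below both wild-type libraries and 2 in the opposite order. Their summed FPKM was 2986 and 7115 in the wild-type mice and 987 and 971 in the knockout mice, a ratio of 0.194 between genotypes that was 0.328 without wild-type mouse 2. Ighm, the constant region of IgM, measured 245 ± 29.2 in wild type and 53.1 ± 23.4 in the knockout (SD, n = 2, log2 difference -2.25, SE 0.33, adjusted p = 0.641). Igkc, the kappa constant region, measured 1087 ± 542 and 291 ± 51.8, Ighg2b 5.09 ± 0.98 and 1.66 ± 0.57, and Jchain, which joins IgA and IgM polymers, 104 ± 72.0 and 15.4 ± 6.80. Mzb1, a chaperone of antibody-secreting cells, measured 8.55 ± 1.17 and 4.57 ± 0.47. Xbp1 and Tnfrsf17, named after their values were seen, were not lower in both knockout mice. Xbp1 had 83.2 and 79.7 in wild type and 67.0 and 82.9 in the knockout. Tnfrsf17, too low to be tested, had 0.0658 and 0.172 against 0.473 and 0.372. Neither gene can decide whether antibody-secreting cells were fewer. Tnfrsf17 lay near the floor, and Xbp1 was measured in whole tissue and not assigned to a cell type. None of the 155 genes passed over all genes tested (smallest adjusted p = 0.187). In the fixed list of B cell and plasma cell genes, 18 of 20 tested members were lower, 4 passed when adjusted over the list alone and 0 over all genes. The list was lower by camera (median log2 difference -0.34, adjusted p = 3.5e-05). The call was lost with adjusted p = 0.646 with an estimated correlation, and without knockout mouse 2 (median 0.05, adjusted p = 0.194). Of these members, 11 B cell surface and transcription factor genes, grouped after their values were seen, were all lower (median -0.32), but 7 of 11 were lower without wild-type mouse 2 and 2 of 11 without knockout mouse 2. Among them Cd79a, named after its values were seen, overlapped between genotypes, with 14.0 and 20.1 in wild type and 23.8 and 10.0 in the knockout.

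**Figure D2:**
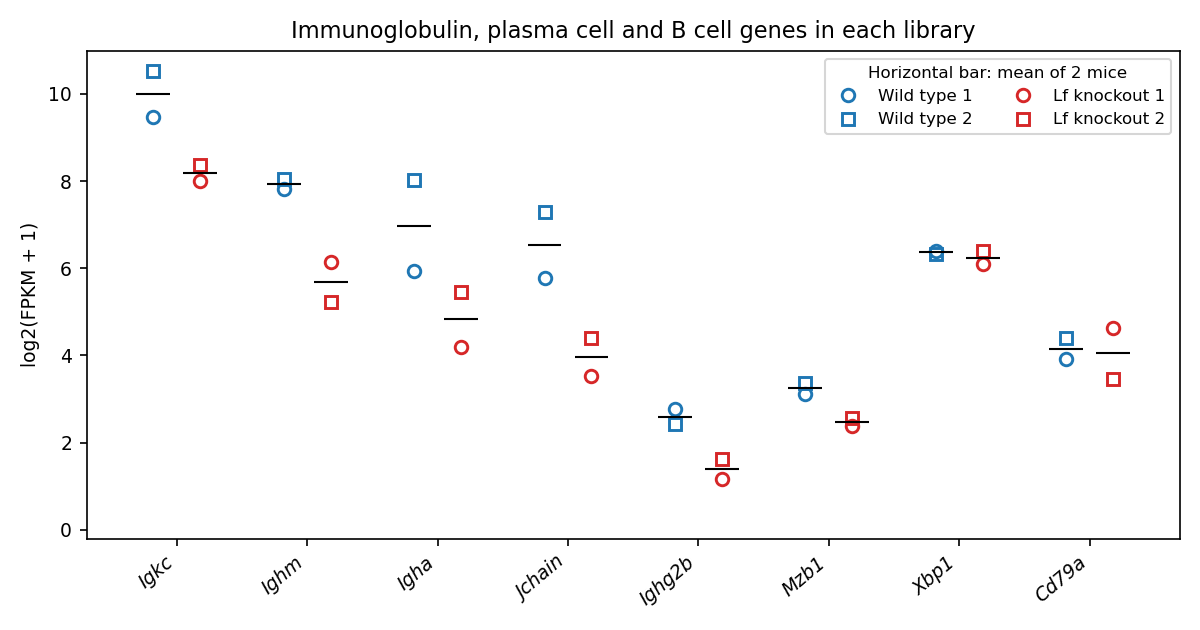
Each point is 1 library's log2(FPKM + 1) for immunoglobulin genes, genes of antibody-secreting cells and B cell genes, with wild-type mice in blue and Lf knockout mice in red; horizontal bars are means of 2 mice. Igkc, Ighm, Igha, Jchain, Ighg2b and Mzb1 lie lower in both knockout mice, and the genotypes overlap for Xbp1 and Cd79a; Igha, Xbp1 and Cd79a were chosen after their values were seen.

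Proliferation genes were lower as a list in the knockout lung. All 20 tested members of the list were lower, 17 with both knockout libraries below both wild-type libraries. Top2a, a topoisomerase of dividing cells, measured 3.11 ± 0.61 in wild type and 1.20 ± 0.42 in the knockout, Mki67, the Ki-67 antigen, 1.87 ± 0.40 and 0.766 ± 0.14, Rrm2 3.26 ± 0.99 and 1.56 ± 0.05, and Prc1 1.78 ± 0.25 and 0.742 ± 0.11 (SD, n = 2). The list had the smallest p of the 36 tested (median log2 difference -0.46, camera adjusted p = 1.4e-10), against adjusted p = 0.646 with an estimated correlation. No member passed alone. The list deviated by 0.34 in wild-type mouse 2, where melanocyte genes deviated by 1.75, and by -0.36 in knockout mouse 2, where alveolar macrophage genes deviated by -1.28. Its median was -0.59 without wild-type mouse 1 and -0.35 without wild-type mouse 2. It was -0.57 without knockout mouse 1 and -0.42 without knockout mouse 2. At a mean FPKM of at least 5 the list had under 5 members and was not tested.

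Neutrophil granule genes were lower as a list, and neutrophil surface and suppressor cell markers did not pass. Of 12 tested granule genes other than Ltf, 11 were lower and 9 did not overlap between genotypes. The list was lower by camera (median -0.72, adjusted p = 2.0e-06, and adjusted p = 0.646 with an estimated correlation). Its estimated correlation was -0.03, under the preset 0.01, so members varying together do not account for that lost call. Ngp measured 10.5 and 21.5 in wild type and 0.392 and 4.29 in the knockout, and Camp, the cathelicidin precursor, 6.69 and 12.1 against 0.306 and 3.39. Both genes lie on chromosome 9 near Ltf, Ngp from 110419747 and Camp from 109847379, and an effect of that position was not tested. Cd177 measured 4.17 ± 0.45 against 2.12 ± 0.30. With Chil1, 2 members passed when adjusted over the list alone and 0 over all genes. Among 25 neutrophil and myeloid suppressor cell markers 11 were higher and 14 lower (median -0.07, adjusted p = 0.85), with a median of -0.25 without knockout mouse 2, past the threshold (adjusted p = 0.0070), and 0.10 without knockout mouse 1 (adjusted p = 0.0598). The difference between these lists was not tested. Il1b measured 11.6 ± 1.10 in wild type and 17.1 ± 0.61 in the knockout, Csf3r 10.5 ± 0.11 and 14.8 ± 2.85, and Itgam 8.27 ± 0.02 and 5.48 ± 1.4. Of 15 tested chemokines that recruit neutrophils and monocytes 12 were lower, among them Ccl9 (12.9 ± 1.5 and 6.25 ± 0.78), Ccl6 (198 ± 3.48 and 72.9 ± 52.9) and Cxcl15 (814 ± 47.5 and 583 ± 90.8), while Ppbp measured 17.98 ± 3.08 and 34.0 ± 17.1. The chemokine list was lower (median -0.29, adjusted p = 0.0137, and adjusted p = 0.648 with an estimated correlation). That call was lost without wild-type mouse 1 (median -0.24) or knockout mouse 2 (median -0.06). It was also lost with no filter (median -0.18, adjusted p = 0.0783) and at a mean FPKM of at least 5 (median -0.49, adjusted p = 0.061).

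As list means, macrophage genes were lowest in knockout mouse 2. Of 17 alveolar macrophage markers 15 were lower in the knockout (median -0.96, camera adjusted p = 2.8e-05, and adjusted p = 0.646 with an estimated correlation). Chil3 had an FPKM of 352 and 336 in the wild-type mice and 204 and 28.0 in knockout mice 1 and 2, and Atp6v0d2 13.3 and 17.7 against 11.8 and 2.15. Of 18 monocyte and interstitial macrophage markers 17 were lower (median -0.68, adjusted p = 2.0e-05, and adjusted p = 0.646 with an estimated correlation). C1qa had 72.1 and 63.8 against 52.3 and 17.4, and Lyve1 134 and 148 against 83.3 and 113. Without knockout mouse 2 the medians of these lists were -0.13 and -0.23, still past the threshold (adjusted p = 0.0048 and 0.0038).

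Toll-like receptor, natural killer and T cell genes were lower as lists. Of 23 Toll-like receptors and adaptors 19 were lower (median -0.20, camera adjusted p = 0.00072, and adjusted p = 0.646 with an estimated correlation). Tlr8 measured 4.97 ± 2.75 in wild type and 1.32 ± 1.14 in the knockout, and Tlr13 4.77 ± 1.94 and 2.79 ± 0.67. Both of these genes lie on chromosome X. Tlr9, on chromosome 9, measured 2.31 ± 0.52 and 1.05 ± 0.78. Of 11 natural killer genes 10 were lower (median -0.51, adjusted p = 0.0009, and adjusted p = 0.646 with an estimated correlation). Gzma, a granzyme, measured 19.8 ± 6.73 and 10.1 ± 4.59, and Klrd1 1.67 ± 0.29 and 2.55 ± 0.27. All 13 tested T cell genes were lower (median -0.32, adjusted p = 0.00072, and adjusted p = 0.687 with an estimated correlation). Cd4 measured 3.48 ± 0.26 and 1.54 ± 0.59, and Lck 6.45 ± 0.32 and 4.87 ± 0.93. The T cell call was lost without wild-type mouse 2 (adjusted p = 0.0825) or knockout mouse 2 (median -0.0008, adjusted p = 0.624). Without knockout mouse 2 the medians of the Toll-like receptor and natural killer lists were -0.09 and -0.12. At a mean FPKM of at least 5 the Toll-like receptor call was lost (median -0.07, adjusted p = 0.102), and the natural killer and T cell lists had under 5 members and were not tested.

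As lists at the preset correlation, alveolar type 2 genes were lower, and type 1, endothelial and platelet genes higher, with no member past the threshold alone. Of 18 type 2 genes 17 were lower (median -0.46, camera adjusted p = 0.0003, and adjusted p = 0.646 with an estimated correlation), among them the surfactant protein gene Sftpd (1048 ± 199 in wild type, 658 ± 13.8 in the knockout) and Muc1 (169 ± 26.6 and 115 ± 20.2), while the transcription factor gene Nkx2-1 measured 72.6 ± 2.60 and 90.5 ± 9.25. Of 15 type 1 genes 13 were higher (median 0.32, adjusted p = 0.0009, and adjusted p = 0.667 with an estimated correlation). Ager measured 884 ± 125 and 1248 ± 229, and Cav1, of caveolae, 339 ± 22.4 and 435 ± 37.7. Of 25 endothelial genes 21 were higher (median 0.19, adjusted p = 0.00076, and adjusted p = 0.646 with an estimated correlation), among them Egfl7 (63.3 ± 4.35 and 87.0 ± 1.03), Ramp2 (74.3 ± 2.23 and 99.3 ± 11.9) and the VEGF receptor gene Kdr (68.4 ± 2.98 and 85.6 ± 7.09). Vwf measured 90.5 ± 32.2 and 58.8 ± 3.50. Of 14 platelet and megakaryocyte genes 12 were higher (median 0.33, adjusted p = 0.0009, and adjusted p = 0.667 with an estimated correlation), with Gp5 at 1.70 ± 0.60 and 4.43 ± 1.87 and Tubb1 at 6.26 ± 1.81 and 11.0 ± 2.02. The type 1 call was lost without wild-type mouse 1 (median 0.15, adjusted p = 0.543) or knockout mouse 2 (median 0.15, adjusted p = 0.214), the endothelial call without wild-type mouse 1 (median 0.11, adjusted p = 0.34) and the platelet call without knockout mouse 2 (median 0.18, adjusted p = 0.266). Without knockout mouse 2 the type 2 median was -0.16.

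Iron handling genes other than Ltf were lower as a list. Of 26 tested members 19 were lower (median -0.20, camera adjusted p = 0.0012, and adjusted p = 0.646 with an estimated correlation). Tfrc, the transferrin receptor, measured 24.3 ± 0.70 in wild type and 16.7 ± 4.10 in the knockout, Cp, the ferroxidase ceruloplasmin, 44.0 ± 8.36 and 31.3 ± 0.52, and Slc11a1, a metal transporter of phagosomes, 7.64 ± 1.11 and 4.89 ± 1.31. Of 24 metastatic niche and matrix remodelling genes 17 were lower (median -0.18, adjusted p = 0.0255, and adjusted p = 0.646 with an estimated correlation), with fibronectin (Fn1) at 67.3 ± 7.17 and 43.4 ± 2.69 and Mmp2 at 45.8 ± 6.70 and 27.5 ± 9.55. Of 20 cytosolic ribosomal protein genes 18 were higher (median 0.10, adjusted p = 0.0125, and adjusted p = 0.646 with an estimated correlation), such as Rps14 (42.1 ± 2.60 and 51.8 ± 3.45). Of 25 immediate early and heat shock genes 15 were higher and 10 lower (median 0.07, adjusted p = 0.0389, and adjusted p = 0.687 with an estimated correlation). Jun measured 108 ± 0.60 and 141 ± 2.80, and the chaperone gene Hspa8 21.3 ± 4.99 and 13.6 ± 0.50. The niche call was lost without wild-type mouse 1 (median -0.04, adjusted p = 0.318) or knockout mouse 1 (adjusted p = 0.339), the ribosomal call without wild-type mouse 1 (median 0.17, adjusted p = 0.0523) or knockout mouse 1 (adjusted p = 0.142), and the immediate early call without wild-type mouse 1 (median 0.18, adjusted p = 0.0748) or knockout mouse 2 (median -0.03, adjusted p = 0.84). With no filter the niche call was lost (median -0.15, adjusted p = 0.0783), and at a mean FPKM of at least 5 the ribosomal and immediate early calls (medians 0.10 and 0.15, adjusted p = 0.102 for both). The immediate early call was also lost after quantile normalization (median 0.07, adjusted p = 0.129) and with chromosome 17 between 20 and 40 Mb left out (median 0.07, adjusted p = 0.0741), an alternative chosen after seeing the data.

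Melanocyte, adipocyte and MHC class II lists passed in the lower direction, and each lost its call without a single library. Melanoma genes were read in wild-type mouse 2 although the labels place the tumour outside the sample. Mlana measured 4.53 and 21.7 in the wild-type mice and 2.92 and 2.00 in the knockout mice. Pmel, named after its values were seen, measured 0.216 and 30.8 against 1.26 and 0.186. All 6 tested members were lower (median -1.56, camera adjusted p = 0.002, and adjusted p = 0.646 with an estimated correlation), but without wild-type mouse 2 the median was -0.20 (adjusted p = 0.382). All 12 adipocyte genes were lower (median -1.06, adjusted p = 0.00064, and adjusted p = 0.646 with an estimated correlation). Fabp4, named after its values were seen, had 153 in wild-type mouse 1 and 7.66 in wild-type mouse 2, against 7.59 and 11.3, and Scd1 911 and 1021 against 730 and 273. Without wild-type mouse 1 the adipocyte median was 0.01 (adjusted p = 0.543). Of 19 MHC class II genes 16 were lower (median -0.27, adjusted p = 0.0484, and adjusted p = 0.889 with an estimated correlation), and the call was lost without wild-type mouse 2 (median -0.05, adjusted p = 0.814) or knockout mouse 2 (median 0.21, adjusted p = 0.289). It was also lost with no filter (median -0.26, adjusted p = 0.114), at a mean FPKM of at least 5 (median -0.24, adjusted p = 0.138) and with chromosome 17 between 20 and 40 Mb left out (median -0.35, adjusted p = 0.065).

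**Figure D3:**
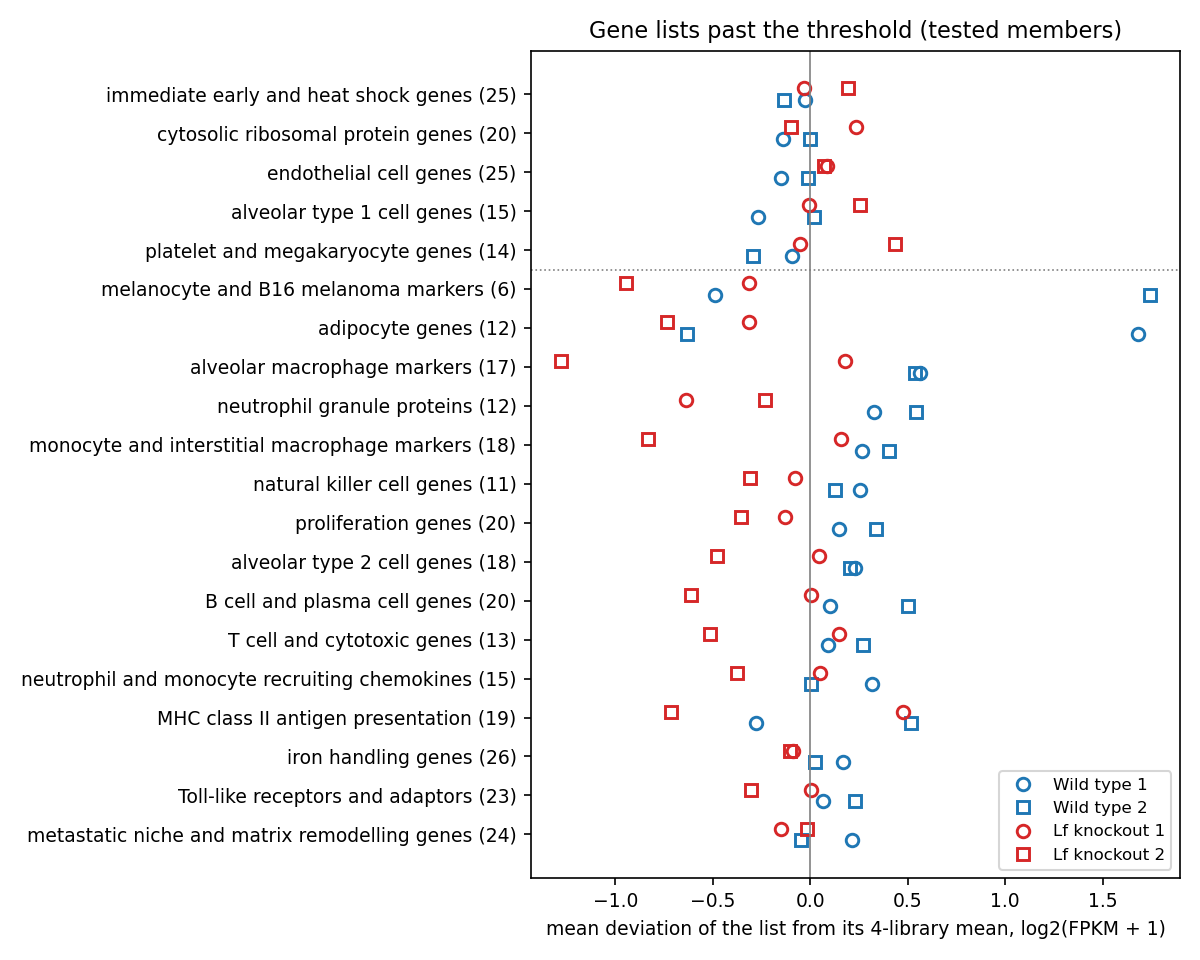
Each point is 1 library's mean deviation over a list's tested members, in log2(FPKM + 1), from the list's mean over 4 libraries, for the 20 lists past the threshold with the preset correlation; wild-type mice are blue and Lf knockout mice red, and the 5 lists above the dotted line are higher in the knockout. Alveolar macrophage genes deviate by -1.28 in knockout mouse 2 and melanocyte genes by 1.75 in wild-type mouse 2.

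Several large differences between libraries did not follow genotype, and these genes were chosen after their values were seen. H2-Eb1, a class II chain (chromosome 17, 34305867 to 34316674), had an FPKM of 7.67 in wild-type mouse 1 and 5.97 in knockout mouse 2, against 314 in wild-type mouse 2 and 326 in knockout mouse 1. H2-Aa had 71.4 and 46.5 in the first pair and 513 and 516 in the second, and H2-Ab1 165 and 118 against 461 and 471. Cd74, a class II partner outside chromosome 17, had 1019 and 550.5 in the first pair and 1099.5 and 1048 in the second. The atrial peptide gene Nppa had 293 in wild-type mouse 1 and 108 in knockout mouse 2, against 1.05 and 1.45 in wild-type mouse 2 and knockout mouse 1. Scgb1a1, the club cell secretory protein and the most abundant transcript of the other 3 libraries at 60454 to 72936, was listed at 0 in knockout mouse 2. Gapdh was listed at 0.0458 to 0.0893 in all 4 libraries. Listed values near 0 in these files can therefore stand for a failed estimate.

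**Figure D4:**
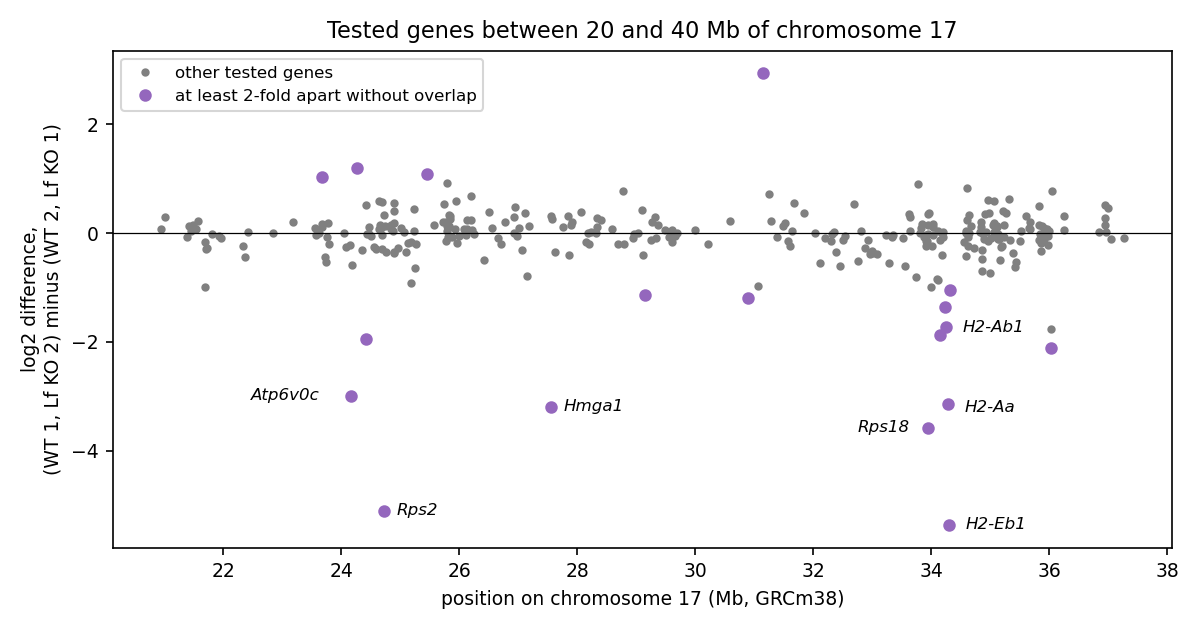
Each point is 1 of 323 tested genes at its position between 20 and 40 Mb of chromosome 17; the vertical axis is the log2 difference between the mean of wild-type mouse 1 and knockout mouse 2 and the mean of wild-type mouse 2 and knockout mouse 1. Purple points are the 18 genes at least 2-fold apart without overlap, 14 of them lower in wild-type mouse 1 and knockout mouse 2.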

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

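Leaving out chromosomes X and Y, immunoglobulin genes or chromosome 17 between 20 and 40 Mb was chosen only after the results were seen. Ltf was lower in the knockout under every alternative run and passed under none. Of the 2 genes higher in the knockout by limma, 1 passed at a mean FPKM of at least 5. With no filter 0 passed (379 at an unadjusted p under 0.05), and with the replicate block 0 (153). Leaving out X and Y removes these 2 genes, which are Y-linked, and 0 others passed in the higher direction (306). The 1 lower gene became 0 with a pseudocount of 0.1 (308 at an unadjusted p under 0.05), no filter (508), median ratio scaling (332), quantile normalization (251), constant prior variance (349), robust eBayes (311), the replicate block (265) and X and Y left out (306). Same-numbered libraries deviated from their group means with a correlation of -0.34 over 12573 genes, and the block left 5 lists higher and 16 lower, of which fibroblast and matrix genes (adjusted p = 0.0356) had not passed without it. Genes at least 2-fold higher numbered 33 with a pseudocount of 0.1 and 7 at a mean FPKM of at least 5, where 8397 genes were tested. Genes at least 2-fold lower numbered 208 with a pseudocount of 0.1, 57 with haemoglobin, immunoglobulin and top 20 genes left out and 56 with immunoglobulin genes left out, which removes genes of that count. Lists higher and lower numbered 3 and 9 at a mean FPKM of at least 5, and 0 and 0 with the estimated correlation. Of the 20 list calls, 17 remained with no filter, 12 at a mean FPKM of at least 5 (where 3 of the lost lists had under 5 members), 19 after quantile normalization and 18 with chromosome 17 between 20 and 40 Mb left out. Among lists that did not pass, camera's direction turned with no filter for suppressor cell markers (median -0.066) and cardiac genes (median -0.067), whose medians did not move, and for erythroid genes, whose median turned to -0.083. It turned at a mean FPKM of at least 5 for interferon-stimulated (median 0.14) and smooth muscle genes (median 0.077), and for the latter with chromosome 17 between 20 and 40 Mb left out (median 0.047), with no change in the sign of these medians. Rps2 reversed to -0.13 with a pseudocount of 0.1. Where no construction is named, the cause was not tested.

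Leaving out 1 library leaves a genotype with 1 mouse, assumed to vary like the other genotype. Across these fits 0 to 0 genes were higher and 0 to 1 lower, 24 to 72 were at least 2-fold higher and 157 to 319 lower, and 3 to 7 lists were higher. Medians that changed sign ranged from -0.27 to 0.0315 for MHC class I, -0.84 to 0.21 for MHC class II, -1.83 to 0.0066 for adipocyte, -1.14 to 1.01 for cardiac, -0.26 to 0.055 for cholesterol, -0.27 to 0.30 for ciliated and -2.31 to 0.28 for club cell genes. They ranged from -0.22 to 0.18 for erythroid, -0.43 to 0.22 for fibroblast, -0.029 to 0.33 for immediate early, -0.14 to 0.13 for interferon and -0.25 to 0.10 for suppressor cell genes. Oxidative phosphorylation ranged from -0.12 to 0.30, oxidative stress from -0.14 to 0.083, skeletal muscle from -0.52 to 0.80 and smooth muscle from -0.62 to 0.43. B cell and plasma cell genes ranged from -0.79 to 0.05, hypoxia genes from -0.07 to 0.04 and circadian genes from -0.13 to 0.0028. Genes that changed sign were Bpifa1 (-6.81 to 2.55), Cd79a (-0.69 to 0.47), Fabp4 (-3.90 to 0.25), H2-Aa (-2.02 to 1.42), H2-Ab1 (-1.22 to 0.77), H2-Eb1 (-2.91 to 2.65), Nppa (-4.17 to 2.99), Pmel (-4.28 to 0.43), Reg3g (-4.72 to 2.20), Rps18 (-1.81 to 1.78), Rps2 (-2.59 to 2.75), Scgb1a1 (-16.02 to 0.076) and Xbp1 (-0.28 to 0.025). Read depth is unknown, so what depth limits could not be computed.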

Other observations

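The tests of explanations below were all chosen after the results they bear on were seen. Of the 36 gene lists tested, 16 did not pass. Some of their members lay apart between genotypes, an order that chance gives to 1 in 6 genes per direction. The members named below are examples, and their lying apart is not a sign of a genotype difference. Among circadian clock genes, Nr1d1 (42.8 ± 11.6 in wild type, 24.1 ± 3.39 in the knockout, SD, n = 2), Nr1d2 (9.86 ± 0.51 and 6.04 ± 0.66) and Bhlhe40 (17.5 ± 0.85 and 11.4 ± 1.81) were lower. In that list 7 of 19 members were higher (camera adjusted p = 0.245) and 0 passed alone. The genotypes did not overlap for 4 of the 19 in each direction, where chance gives 1 in 6 per direction. Of 22 oxidative stress genes 10 were higher (adjusted p = 0.68, median -0.06 and mean 0.02), with Gclc at 70.9 ± 7.47 and 47.7 ± 0.35, Sod1 at 163 ± 11.8 and 204 ± 17.5 and Sod3 at 109 ± 31.5 and 158 ± 3.66. Hk2 measured 6.65 ± 0.70 and 3.72 ± 0.63 in a hypoxia and glycolysis list with 8 of 19 members higher (adjusted p = 0.467). Of 27 interferon-stimulated genes 14 were higher (adjusted p = 0.872, median 0.01 and mean -0.03), and Oas2 measured 3.46 ± 0.97 and 1.30 ± 0.19 while Ifit3 measured 21.5 ± 9.41 and 33.4 ± 5.87. In MHC class I 7 of 18 genes were higher (adjusted p = 0.357), in fibroblast and matrix genes 8 of 25 (adjusted p = 0.467), in cholesterol synthesis 7 of 21 (adjusted p = 0.236) and among genes near Ltf 7 of 18 (adjusted p = 0.313). Oxidative phosphorylation had 17 of 24 members higher (adjusted p = 0.234), ciliated cells 10 of 19 (adjusted p = 0.85), erythroid cells 6 of 12 (adjusted p = 0.619, median 0.01 and mean -0.19) and skeletal muscle 3 of 5 (adjusted p = 0.352). Smooth muscle had 7 of 14 higher (adjusted p = 0.872, median 0.01 and mean -0.03), and the mast cell list had 3 measured members, too few for its test. Leaving out 1 library brought calls for several of these lists. Without wild-type mouse 1, MHC class I was lower (adjusted p = 0.0115) and ciliated (0.0115), oxidative phosphorylation (0.00038), skeletal muscle (0.0044) and smooth muscle genes (0.00013) higher. Without wild-type mouse 2, fibroblast (adjusted p = 0.00013), smooth muscle (2.2e-06), cholesterol (0.00014) and ciliated genes (0.0129) were lower and erythroid genes (0.0364) higher. Without knockout mouse 1, ciliated (adjusted p = 0.0012) and oxidative phosphorylation genes (0.0049) were higher, and without knockout mouse 2 ciliated genes (0.0031) were lower and interferon-stimulated genes (0.019) higher.

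Wild-type mouse 1 carried transcripts that were scarce in the other 3 libraries, named after their values were seen. Ucp1, the uncoupling protein of brown fat, had an FPKM of 45.3 there and 0.0271 to 0.118 elsewhere, and the secreted airway proteins Bpifa1 and Reg3g had 1740 and 237 there against at most 24.4 and 17.7 elsewhere. Of 15 club and goblet cell genes 4 were higher in the knockout (camera adjusted p = 0.188), and the list deviated by 2.00 on the log2 scale in wild-type mouse 1. It was higher without that mouse (adjusted p = 0.0349), and lower without wild-type mouse 2 (adjusted p = 5.7e-09) or knockout mouse 2 (adjusted p = 0.0276). Of 21 cardiac genes 5 were higher (adjusted p = 0.85), and 20 were higher in both wild-type mouse 1 and knockout mouse 2 than in both other mice, with a median difference of 1.84. The cardiac list was higher without wild-type mouse 1 (adjusted p = 0.00013) or knockout mouse 1 (adjusted p = 0.0206), and lower without wild-type mouse 2 (adjusted p = 4.3e-07) or knockout mouse 2 (adjusted p = 0.0038).

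The 4 libraries can be split into pairs in 3 ways, too few for a share of splits under 0.05. The genotype split gave 3 genes past the threshold, and the highest of the other splits gave 10, so that 2 of the 3 splits gave at least 3. That other split sets wild-type mouse 1 and knockout mouse 2 against wild-type mouse 2 and knockout mouse 1. Of its 10 genes, 5 lie on chromosome 17: H2-Eb1, Rps2, Rps18, Atp6v0c and Hmga1. Explanations for that chromosome are weighed below. For the other genes of the 10, a structure of the samples other than genotype was not tested.

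Y-linked transcripts were near 0 in both wild-type mice. Failed estimates of single genes would fall on any chromosome, but all 4 genes under 0.05 in both wild-type mice and at 1 or more in both knockout mice lie on Y. That the wild-type libraries came from female mice is a candidate explanation: 4 X-linked genes that escape silencing had a median log2 difference of -0.69, against -0.02 (SD 0.24) for 350 other X genes, and 0.01% of 10000 random draws of 4 X genes gave as low a median. The 4 genes were chosen after their values were seen, so that share describes their position and is not a test. The labels call every mouse male. All 4 Y-linked genes that reached an FPKM of 1 in a library were under 0.05 in both wild-type mice. They had between 1.91 and 24.2 in both knockout mice. Loss of lactoferrin as the cause, in mice that were all male, would leave Y-linked genes present in the wild-type mice. The values argue against that cause for these 4 Y-linked genes. Whether genotype plays a part in the X-linked difference was not tested.

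Genes of chromosome 17, chosen after their values were seen, separated wild-type mouse 1 and knockout mouse 2 from the other mice. Fewer antigen-presenting cells would lower class II partners elsewhere, but between these pairs of mice 11 list members outside chromosome 17 had a median log2 difference of -0.33 (SD 0.20), against -3.14 for H2-Eb1, H2-Aa and H2-Ab1. Reads shared with near-identical copies are argued against by the 0 annotated copies of these 3 genes, though Rps2 and Rps18, also apart, have 23 and 5. Another sequence haplotype around the H2 genes, read poorly against the reference, may contribute: 18 of 323 genes between 20 and 40 Mb were at least 2-fold apart, against 170 of 11935 elsewhere (odds ratio 4.08, 3.04 without the genes past the threshold). H2-Aa and H2-Ab1, which are among the genes that prompted the test, still count in the 3.04, so it is not independent of them. The region was chosen after H2-Eb1 was seen, and 4 other 20-Mb windows had higher shares than its 5.57%: those of the immunoglobulin heavy chain (9.89%) and kappa (6.50%) genes, the start of chromosome 13 (8.70%, 4 of 46 genes) and chromosome 7 from 140 Mb (5.80%, 4 of 69 genes).

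Immunoglobulin genes were lower in both knockout mice, with a median log2 difference of -1.37, and -0.86 without wild-type mouse 2. A difference at the heavy chain locus alone is argued against by the light chain genes on other chromosomes (median -1.35 over 82 genes). Fewer B cells of every kind as the whole cause would lower B cell genes as much as immunoglobulin genes. The 11 B cell surface and transcription factor genes had a median of -0.32 (SD 0.13). It was -0.44 (SD 0.17) without wild-type mouse 1 and -0.08 (SD 0.17) without wild-type mouse 2. It was -0.78 (SD 0.21) without knockout mouse 1 and 0.20 (SD 0.19) without knockout mouse 2. Each of these lay above the median of immunoglobulin genes in the same libraries, by over 2 SD. That SD is the spread between genes and not between mice, so a bound in SD cannot decide the question here. The bound of 2 SD was also set after the value was seen. The bound first written, a median above -0.34, lay within the spread of the value and left the test undecided. A smaller B cell share stays open as part of the difference. The loss of lactoferrin and the sex of the mice both stay open: 0 pairs of a wild-type and a knockout library share a Y-gene state, so these cannot be told apart.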
